A study of Drosophila melanogaster with 13 samples.

How the data were processed

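Expression of the Drosophila melanogaster genome in whole testes was measured on 13 Affymetrix Drosophila 2 arrays, 1 per sample, from RNA labelled with a 3' IVT kit. The deposited values are log2 probe set summaries that the authors corrected for background and normalized with GCRMA, whose version the labels do not state. Values of all arrays share a floor of 2.1019, where 27.6% to 32.2% of the probe sets of an array lie. Of 18952 probe sets, 183 are controls, 13647 pair with exactly 1 gene symbol in the platform's table, 402 pair with several and 4903 with none. The gene identifiers of 13544 of the 13647 were found in the gene table of assembly Release 6 plus ISO1 MT, which gave chromosomes and gene spans.

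Genes were analysed through probe sets of exactly 1 gene. A probe set was tested when its log2 value was above 4 in at least 3 of the 13 arrays, and the probe set with the highest mean stood for its gene, which left 8719 genes. Arrays were grouped by genotype as aly, sa, magn and WT, with the 4 magn arrays as 1 group as the series' design text counts them. A linear model was fitted to all arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and contrasts of group means were tested with Benjamini-Hochberg adjustment within each contrast. A gene was called when its adjusted p was under 0.05 and its change at least 2-fold. A second fit with 5 groups compared the 2 magn allele combinations with WT and with each other. Where all arrays of a group lay at or below a log2 value of 4, the fold is given as a bound against 4, written at least N-fold. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

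The groups, tests, gene lists and most alternatives were chosen before the data were examined. There were 23 lists of genes: testis TAFs, tMAC and associated genes, meiotic cell cycle, meiotic chromosomes, spermatid Mst and don juan genes, sperm chromatin, sperm axoneme dyneins and tubulins, testis proteasome paralogs, the general proteasome, ubiquitin supply and recycling, testis mitochondrial and glycolytic paralogs, sperm leucyl aminopeptidases, comet and cup genes, germline stem cells and spermatogonia, spermatocytes, cyst and hub cells, sheath muscle, accessory gland and male duct, fat body, hemocytes, heat shock, apoptosis, and cytosolic ribosomal proteins. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Members called were counted over all genes and adjusted over the list alone. Most lists hold genes that testes also express, and those of other tissues were used only to describe what the samples contained.

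The genes named in the text follow a rule. It names the mutated genes and the strain markers in every array. For each of 5 comparisons it names the 6 largest rises and the 6 largest falls among called genes whose groups of arrays do not overlap, passing over symbols that are only a CG or CR number. Per list it allows up to 4 members with the largest change, any testis TAF or tMAC gene, and twe, bol and CycB. Genes outside the rule appear only among the additional observations.

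The 3 WT arrays serve in several comparisons, so overlaps of calls were set against independence and against 100 simulated draws of unchanged groups. In these draws all arrays, those of WT included, were simulated with independent noise around the WT means, and the groups shared the simulated WT arrays. The replicate numbers of the titles were checked as pairs: of 23 same-numbered pairs, 7 correlated above 0.1 and 11 below 0 (range -0.27 to 0.24), so they were not used to pair arrays in the comparisons reported. The steps were tested on simulated data, where 79% to 87% of genes changed by 1.5 log2 units and 97% to 99% of those changed by 3 were called, with 2 to 7 of 8519 unchanged genes called. There 100 genes per size were changed, in both directions, all well above background and with independent noise. These shares therefore do not carry over to dim genes or to the many changes in the real arrays.

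Alternatives covered the filter, quantile normalization, centring each array on its ribosomal protein genes or on all genes, the variance trend, array weights, the fold minimum, the choice of probe set, the arrays in the fit, the grouping of magn, a replicate block, the list test, and leaving out each array. The number of arrays limits the precision of every value. Probe sets without a gene name were kept out of the comparisons, as were probe sets of several genes, because their signal has no single gene. No scan dates, detection calls or scanner files were at hand, so batches of arrays could not be examined.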

Results

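RNA from whole testes of young adult Drosophila melanogaster males was measured on 13 Affymetrix expression arrays. Testes came from flies with mutations in 3 genes that are needed for spermatocytes to enter meiosis and for spermatids to form, and from a strain that the labels call WT and give as red[1], e[1], or as red[1]/e[1] in the titles. The genotype aly[2]/aly[5p] affects always early, a component of the testis-specific meiotic arrest complex tMAC, and had 3 arrays. The genotype sa[1]/sa[2] affects spermatocyte arrest, which encodes a testis-specific TBP-associated factor (testis TAF), and had 3 arrays. The magellan (magn) flies carry mutations of the polyubiquitin gene Ubi-p63E and had 4 arrays, 2 from magn[12c]/magn[23b] and 2 from magn[12c]/magn[12c];pSC2. The WT strain had 3 arrays. Flies were 0 to 1 day old and were raised at 25 °C, and testes were dissected free of seminal vesicles and accessory glands. Between 8822 and 9759 of the 18952 probe sets lay above a log2 value of 4 in each array, and Pearson's r across probe sets between arrays of the same genotype, with the 2 magn combinations kept apart, ranged from 0.9834 to 0.9962, and between arrays of the 2 magn combinations from 0.9821 to 0.9843. The number of arrays per group limits the precision of each value. The labels call the replicates biological, but do not say whether they came from separate crosses.

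The mutated genes were compared first, in every array. Ubi-p63E stood at 14.76 ± 0.13 (log2, SD, n = 3) in WT and at 4.22 ± 0.85 (n = 4) in magn, where the arrays read 3.93 and 5.47 for magn[12c]/magn[23b] and 3.88 and 3.59 for magn[12c]/magn[12c];pSC2. It fell by 10.55 on the log2 scale in magn, or by 10.40 with values under 4 raised to 4 (SE 0.33, adjusted p = 4.53e-11, limma), read 14.71 ± 0.06 in aly (n = 3; log2 change -0.05, or -1.47 and called lower with arrays centred on ribosomal protein genes), and read 13.67 ± 0.10 in sa (n = 3; log2 change -1.10, adjusted p = 0.0109, limma, and -0.96, not called, after quantile normalization). The sa gene stood at 6.08 ± 0.21 (SD, n = 3) in sa, below the WT level in all 3 arrays (log2 change -4.92, SE 0.16, adjusted p = 1.06e-10, limma). It rose by 2.74 in aly and by 1.39 in magn, where the rise became 0.41 and was not called with arrays centred on ribosomal protein genes. The aly gene read 6.17 ± 0.18 in WT and 7.29 ± 0.06 in aly, a change of 1.12 (SE 0.31, adjusted p = 0.00427, limma) that became -0.29 when each array was centred on its ribosomal protein genes. Transcript of e (ebony), one of the WT strain's marker genes, read 4.11 ± 0.43 in WT and at most 2.69 in any mutant array, and no probe set was named for red.

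**Figure D1:**
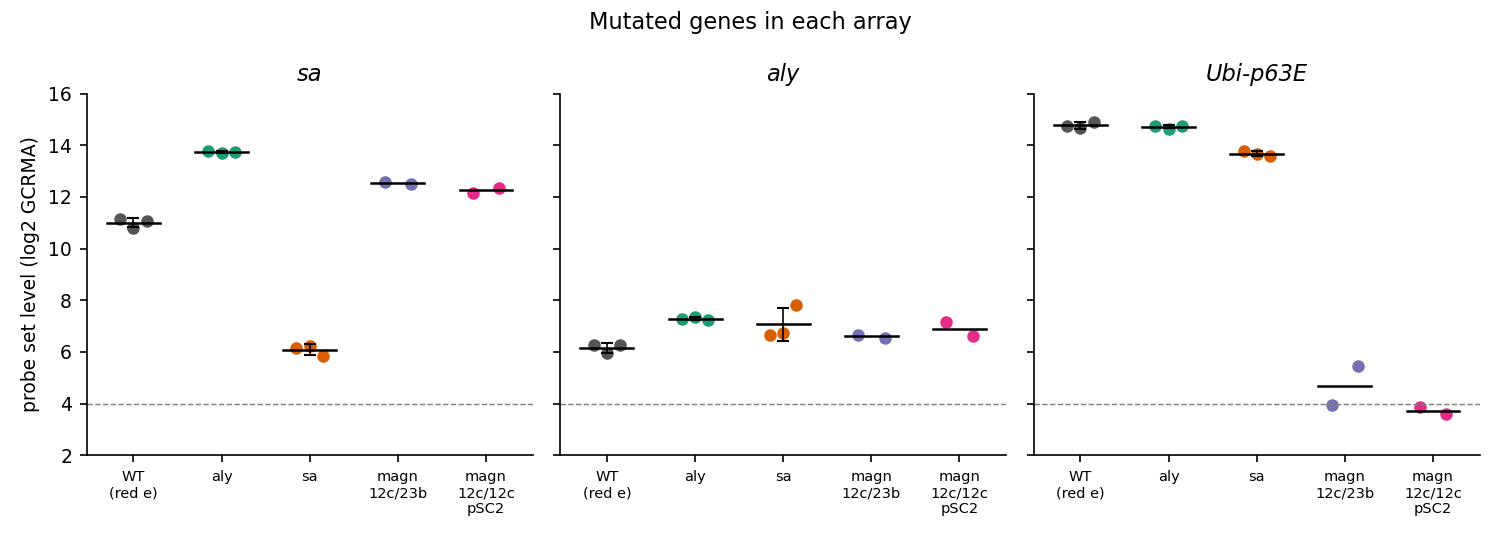
Level of sa, aly and Ubi-p63E in each of the 13 arrays (vertical axis, log2 GCRMA value; points are arrays, horizontal bars are group means, error bars are the SD of groups with 3 arrays, and the dashed line marks the detection level of 4). Ubi-p63E reads at most 5.47 in the magn arrays against 14.76 on average in WT, and sa averages 6.08 in sa mutants, a change of -4.92 against WT.

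Testes mutant for aly were compared with WT to ask which transcripts differ. The mutated genes are needed for spermatids to form, so the mix of germ cells goes with the genotype. In whole testes a change of that mix cannot be told apart from a change of regulation, here and in all comparisons below. Other differences between the WT strain and the mutant flies go with the genotype too, and comparisons with WT cannot set them apart. Many transcripts of late spermatogenesis fell to the background of the arrays. The comet and cup gene w-cup fell from 14.04 ± 0.26 to 2.31 ± 0.13 (log2, SD, n = 3 and 3), at least 1050-fold. The protamine-like chromatin gene Mst33A, the sperm gene saturn, the cytochrome oxidase paralog COX5BL, Rcd7 and the dynein light chain gene robl62A were also at least 751-fold lower, with adjusted p of 5.29e-13 or less (limma). The largest fitted rises were those of PIG-X (at least 76.8-fold), which acts in GPI anchor synthesis, the lysosomal iduronidase gene Idua (at least 56.0-fold), the ribosomal protein paralog RpL22-like (from 5.76 to 12.85, log2 change 7.09, SE 0.22), the nitric oxide synthase gene Nos (at least 39.6-fold), Dlish (at least 51.2-fold) and the inositol phosphatase gene 5PtaseI. In total 6087 of 8719 genes were called, 3966 higher and 2121 lower (limma, adjusted p under 0.05 and at least 2-fold). With values under 4 raised to 4, 1146 of these fell at least 16-fold, against 310 that rose as much.

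Gene lists for the late germline moved down together in aly. Of 13 measured Mst and don juan genes of spermatids, 8 fell, also 8 adjusted over the list alone, among them the sperm tail gene dj (at least 49.5-fold), djl (log2 change -9.42, or -8.97 with values under 4 raised to 4) and the mitofusin gene fzo (at least 113-fold). The list had a camera adjusted p of 5.14e-05 and adjusted p = 0.49 with an estimated correlation. Of 8 sperm chromatin genes 7 fell (7 adjusted over the list alone), including the protamine gene ProtB (log2 change -8.25) and the histone-like Mst77F (-7.40). Its camera adjusted p was 4.7e-05, and adjusted p = 0.49 with an estimated correlation. Of 14 comet and cup genes, a class transcribed after meiosis, 11 fell (11 adjusted over the list alone), with c-cup at least 590-fold lower. Camera gave an adjusted p of 1.81e-05, and adjusted p = 0.49 with an estimated correlation. Testis paralogs of mitochondrial and glycolytic genes fell in 12 of 15 cases and rose in 2 (the same counts adjusted over the list alone), with a list median of -9.04, or -8.32 with dim genes at their bound. ATPsynCF6L was at least 569-fold lower, and the list's camera adjusted p was 4.7e-05, with adjusted p = 0.49 with an estimated correlation. Testis paralogs of proteasome subunits fell in 8 of 13 cases and rose in 2 (the same counts adjusted over the list alone), with Prosalpha6T at least 514-fold and Prosbeta5R1 at least 506-fold lower. Camera gave an adjusted p of 0.00977, and adjusted p = 0.55 with an estimated correlation. Axoneme dynein and tubulin genes fell in 12 of 16 cases (12 adjusted over the list alone), among them Dic61B (at least 83.0-fold) and Dhc16F (at least 61.2-fold). The camera adjusted p was 0.000548, and adjusted p = 0.49 with an estimated correlation. Sperm leucyl aminopeptidase genes fell in 3 of 5 cases, also 3 adjusted over the list alone (camera adjusted p = 0.0176), with adjusted p = 0.55 with an estimated correlation, and S-Lap5 changed by -6.38. After centring on ribosomal protein genes the genes called lower were 13 of 13 for the spermatid list, 8 of 8 for sperm chromatin, 14 of 14 for comet and cup, 13 of 15 for the mitochondrial paralogs, 10 of 13 for the proteasome paralogs, 14 of 16 for the axoneme and 5 of 5 for the aminopeptidases.

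Genes of the transcription machinery that aly belongs to rose in aly testes. All 9 tMAC genes and partners rose, 9 also adjusted over the list alone, with comr at 3.23, topi at 3.14 and tomb at 4.13 (log2 change; list median 2.79, camera adjusted p = 0.0108, and adjusted p = 0.545 with an estimated correlation). All 5 testis TAF genes rose (5 adjusted over the list alone), namely sa, mia (3.02), nht (2.89), can (1.96) and Taf12L (1.24), the last of which changed sign to -0.17 with arrays centred on ribosomal protein genes. That list's camera adjusted p was 0.0319, and adjusted p = 0.545 with an estimated correlation. After that centring 3 of the 5 testis TAF genes and 7 of the 9 tMAC genes were called higher. Meiotic cell cycle genes went both ways in aly, with 5 of 11 higher and 3 lower (the same counts adjusted over the list alone), or 1 higher and 4 lower after centring on ribosomal protein genes. Among those that fell, the Cdc25 gene twe changed by -1.82 (SE 0.27), its translational activator bol by -4.52 (SE 0.34) and CycB by -3.27 (SE 0.46), with adjusted p of 1.89e-05, 1.97e-08 and 1.29e-05 (limma, n = 3 and 3). Early germline genes such as bam (4.85), zpg (3.53) and spn-E (3.29), and the synaptonemal complex gene c(2)M (at least 21.0-fold), rose. The stem cell and spermatogonia list as a whole (9 of 15 higher, 2 lower, the same counts adjusted over the list alone) was not called (camera adjusted p = 0.319). Its median of 1.31 became -0.11 when arrays were centred on ribosomal protein genes. Genes of the general proteasome rose in 22 of 26 cases (22 adjusted over the list alone; Prosbeta2 by 2.96), with a median of 1.60 that shrank to 0.18 after that centring, which left 4 higher and 1 lower. Camera gave that list an adjusted p of 0.000108, and adjusted p = 0.55 with an estimated correlation. Ribosomal protein genes rose in 29 of 36 cases and fell in 2 (the same counts adjusted over the list alone), with RpL37-2 at 3.23 and the testis paralogs RpL10Aa (at least 726-fold lower) and RpS28a (-6.24) the ones that fell. Camera gave 0.000276 for the list, and adjusted p = 0.627 with an estimated correlation. Not called were the lists of meiotic chromosome genes (median 2.20), meiotic cell cycle genes (0.55), spermatocyte genes (-0.95), ubiquitin genes (-0.05), cyst and hub cell genes (0.03), fat body genes (-1.62), hemocyte genes (1.42, or 1.09 with dim genes at their bound), heat shock genes (-0.10) and apoptosis genes (1.39), with camera adjusted p from 0.141 to 0.91. After centring on ribosomal protein genes the medians of the meiotic cell cycle, cyst and hub, and apoptosis lists were -0.86, -1.38 and -0.02.

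Genes of other tissues differed as well. Sheath muscle genes fell in 4 of 14 cases (4 adjusted over the list alone; camera adjusted p = 0.0365, and adjusted p = 0.627 with an estimated correlation), the large muscle genes sls (-5.98, or -5.05 with values under 4 raised to 4) and Msp300 (-5.71) most, and the fat body lipoprotein gene apolpp changed by -7.65, or -7.39 with values so raised. Accessory gland genes were lower in 11 of 20 cases but in 1 adjusted over the list alone (camera adjusted p = 0.0118, and adjusted p = 0.63 with an estimated correlation), and Dup99B at -5.50 (SE 1.80) had overlapping arrays and was not called without aly replicate 3 (-4.03) or WT replicate 2 (-4.11). The median of that list ranged from 9.05 to 13.12 among the WT arrays, highest in WT replicate 2, and from 7.31 to 8.70 among the aly arrays. All 14 sheath muscle and all 20 accessory gland genes were called lower after centring on ribosomal protein genes. The 3' minus 5' signal of actin 5C, a sign of RNA breakdown, was 2.27 to 2.73 in the aly arrays and 1.23 to 1.70 in WT. The same signal of the other controls overlapped between aly and WT, at 2.55 to 2.71 and 2.27 to 2.79 for eIF4a and 1.22 to 1.52 and 1.08 to 1.29 for GAPDH. The signal of 18S ribosomal RNA also differed between the groups, at 7.36 to 7.79 in WT, 9.34 to 10.42 in aly, 10.31 to 12.75 in magn, and 6.99, 12.92 and 12.61 in sa. The median change over all tested genes was 0.77, and ribosomal protein genes moved by 1.43. With arrays centred on these genes, which shifted aly against WT by 1.41, 1738 genes were called higher and 3750 lower, so that 31.7% of the calls were higher in place of 65.2%.

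Testes mutant for sa, which encodes a testis TAF, were compared with WT in the same way. The same kinds of transcript fell as in aly, with smaller changes for many genes. The largest fitted falls were those of t-cup (log2 change -8.57, SE 0.68), lobo (-7.99), an axonemal gene, Mst36Fa (-7.60), shps (-7.52, SE 1.21), the acylphosphatase gene Acyp (-7.49) and Vha36-2 (-7.49), a vacuolar ATPase subunit, each with n = 3 and 3 and adjusted p of at most 6.05e-05 (limma). All but Acyp read under 4 in some sa arrays, and with values under 4 raised to 4 the changes of t-cup, lobo, Mst36Fa, shps and Vha36-2 were -7.89, -7.59, -7.00, -7.07 and -7.40. The neuropeptide gene CCHa1 rose from 3.00 ± 0.92 to 10.40 ± 0.36 (log2 change 7.39, SE 0.41, or 6.39 with values under 4 raised to 4), and Cyp6a2, a cytochrome P450, Hasp, Spn (spinophilin), the Rab gene RabX2 and the serpin gene Spn43Aa rose as well, Cyp6a2 at least 29.5-fold and Spn at least 32.4-fold. In total 5412 genes were called, 3555 higher and 1857 lower, and 364 fell at least 16-fold with values under 4 raised to 4.

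Among the lists, spermatid Mst and don juan genes fell in 9 of 13 cases (9 adjusted over the list alone), with dj at -2.73 and janB at -3.44. The camera adjusted p was 1.77e-06, and adjusted p = 0.359 with an estimated correlation. All 8 sperm chromatin genes fell (8 adjusted over the list alone), with ProtA at -3.69, ProtB at -5.15 and Mst33A at -3.61, where camera gave an adjusted p of 8.14e-06, and adjusted p = 0.359 with an estimated correlation. Comet and cup genes fell in 12 of 14 cases (12 adjusted over the list alone; w-cup -4.74, sunz -4.42; camera adjusted p = 7.62e-07), with adjusted p = 0.359 with an estimated correlation. Axoneme genes fell in 13 of 16 cases (13 adjusted over the list alone), with the Y-linked Ppr-Y at least 8.98-fold lower and Dhc36C at -3.92. The camera adjusted p was 2.04e-05, and adjusted p = 0.359 with an estimated correlation. Testis mitochondrial paralogs fell in 12 of 15 cases and rose in 2 (the same counts adjusted over the list alone; median -2.19; COX6AL2 -6.66, COX5BL -2.40), with a camera adjusted p of 4.43e-05, and adjusted p = 0.415 with an estimated correlation. Testis proteasome paralogs fell in 8 of 13 cases (8 adjusted over the list alone), Prosalpha4T1 by 4.05 and Prosalpha3T by 3.51 on the log2 scale. Camera gave 0.00221, and adjusted p = 0.532 with an estimated correlation. Sperm leucyl aminopeptidase genes fell in 4 of 5 cases, also 4 adjusted over the list alone (camera adjusted p = 0.00187), with adjusted p = 0.415 with an estimated correlation. After centring on ribosomal protein genes the genes called lower were 13 of 13 for the spermatid list, 8 of 8 for sperm chromatin, 14 of 14 for comet and cup, 15 of 16 for the axoneme, 13 of 15 for the mitochondrial paralogs, 11 of 13 for the proteasome paralogs and 5 of 5 for the aminopeptidases.

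The meiotic regulators differed from those in aly. The twe transcript was 7.31 in both sa and WT (log2 change 0.00, SE 0.27, adjusted p = 0.993, limma), or -1.41 and called lower with arrays centred on ribosomal protein genes, bol changed by -1.48 and by -0.93, no longer called, without sa replicate 3, and CycB rose by 2.09 (SE 0.46, adjusted p = 0.000914, limma; 0.68, not called, with arrays centred on ribosomal protein genes). The tMAC gene topi fell by 1.36 while tomb rose by 2.46. Of the testis TAF genes other than sa, mia (1.62), nht (2.15) and Taf12L (2.56) rose, and can read 0.80, under the 2-fold minimum, or -0.60 after centring on ribosomal protein genes, which also ended the calls of mia (0.21) and nht (0.75). That list was not called (camera adjusted p = 0.405). Early germline genes bam (3.56) and zpg (2.52) rose. The stem cell and spermatogonia list (8 of 15 higher, 8 adjusted over the list alone) was not called (camera adjusted p = 0.176), and its median of 1.63 became 0.22 after centring on ribosomal protein genes. General proteasome genes rose in 17 of 26 cases (17 adjusted over the list alone; Prosbeta2 by 2.72), with a median of 1.28 that became -0.13, with 2 higher and 2 lower, when arrays were centred on ribosomal protein genes. Camera gave 2.04e-05, and adjusted p = 0.532 with an estimated correlation. Ribosomal protein genes rose in 30 of 36 cases and fell in 2 (the same counts adjusted over the list alone), among them RpL37-2 at 3.18 and the testis paralog RpS28a at -4.61. Camera gave 8.14e-06, and adjusted p = 0.612 with an estimated correlation. Sheath muscle genes fell in 3 of 14 cases (3 adjusted over the list alone; Act87E -2.19, Msp300 -4.11; camera adjusted p = 0.0423), with adjusted p = 0.616 with an estimated correlation, or in 11 after centring on ribosomal protein genes, and the hub gene esg was at least 10.1-fold lower. The actin 5C 3' minus 5' signal was 2.75, 2.44 and 4.76 in the sa arrays, with replicate 3 apart from the rest. The 13 lists not called in sa had camera adjusted p from 0.065 to 0.787. Among them were meiotic cell cycle genes (median 1.01, and -0.40 after centring on ribosomal protein genes), meiotic chromosome genes (0.86 and -0.55), hemocyte genes (1.25 and -0.16), apoptosis genes (0.97 and -0.44), heat shock genes (0.42 and -0.99) and cyst and hub cell genes (0.15 and -1.26). Spermatocyte genes had a median of -0.16, ubiquitin genes -0.09, fat body genes -1.05 and accessory gland genes -0.79 (1 of 20 lower, 0 adjusted over the list alone, and 12 after centring on ribosomal protein genes). With arrays centred on ribosomal protein genes, a shift of 1.41, 893 genes were higher and 3769 lower, and 19.2% of the calls were higher in place of 65.7%.

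Testes mutant for magn were compared with WT to ask which transcripts differ in testes with mutations of Ubi-p63E. Beside Ubi-p63E itself, the largest fitted falls were those of fipi (log2 change -6.84, SE 0.37), the ribosomal protein paralog RpS28a (-6.56, SE 0.52), the dynein light chain gene robl37BC (-6.55, SE 0.97) and the noncoding lncRNA:CR31526 and lncRNA:CR40465, all with n = 4 and 3. The noncoding falls were not particular to magn. lncRNA:CR31526 averaged 8.69 in WT and 2.1, 2.1 and 2.11 in aly, sa and magn. lncRNA:CR40465 averaged 10.27 in WT and 2.85, 2.81 and 3.96 in aly, sa and magn. With values under 4 raised to 4, fipi, RpS28a and robl37BC changed by -6.48, -6.25 and -6.20. The largest fitted rises were those of CCHa1 (7.51, SE 0.38, or 6.51 with values so raised), RpL22-like (6.90, SE 0.21), RabX2 (6.75, or 6.35), the gustatory receptor gene Gr33a (at least 19.0-fold), the beta-galactosidase gene Ect3 (at least 25.5-fold) and the intraflagellar transport gene IFT52 (at least 46.8-fold). In total 3792 genes were called, 2543 higher and 1249 lower, and 120 fell at least 16-fold with values under 4 raised to 4. Among ubiquitin genes 5 of 13 rose and 2 fell (the same counts adjusted over the list alone). The mutated gene Ubi-p63E is itself a list member and among those that fell. The deubiquitinase genes Usp14 and faf read 1.52 and 1.93, and the Cullin partner Roc1b -3.63. After centring on ribosomal protein genes Usp14 (0.54) and faf (0.95) were not called. The list was not called either (camera adjusted p = 0.765).

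With the 4 magn arrays as 1 group the meiotic regulators were not called: twe changed by -0.23 (adjusted p = 0.441), bol by -0.45 (adjusted p = 0.239) and CycB by -0.30 (adjusted p = 0.560, all limma, n = 4 and 3). After centring on ribosomal protein genes these changes became -1.21, -1.42 and -1.28, each called lower. The CycB value joins 2 unlike groups. CycB read 8.03 and 8.39 in magn[12c]/magn[23b], above all WT arrays (mean 7.71). It read 6.98 and 6.22 in magn[12c]/magn[12c];pSC2, below all WT arrays. Of the 11 meiotic cell cycle genes, 2 were lower and 3 higher than WT in magn[12c]/magn[12c];pSC2. In magn[12c]/magn[23b] 0 were lower and 2 higher. None of the 13 spermatid Mst and don juan genes was called (0 also adjusted over the list alone): dj read 0.88 (adjusted p = 0.0663, limma), or -0.10 with arrays centred on ribosomal protein genes, janB -0.44 and Mst36Fa -1.36, while the list median of -0.27 had a camera adjusted p of 0.0498, and adjusted p = 0.667 with an estimated correlation. After centring on ribosomal protein genes that median was -1.25 and 9 of the 13 were called lower. Of 8 sperm chromatin genes 1 fell (1 adjusted over the list alone), the transition protein gene Tpl94D by 1.72 on the log2 scale, and ProtB read -0.72. The camera adjusted p was 0.021, and adjusted p = 0.6 with an estimated correlation. Axoneme genes fell in 10 of 16 cases and rose in 1 (the same counts adjusted over the list alone; median -1.43), with the Y-linked ORY at -4.16 and Ppr-Y at -3.63 (-3.62 and -2.84 with values under 4 raised to 4) and the dynein heavy chain genes Dhc36C at -3.69 and Dhc16F at -3.09. Camera gave 0.000114, and adjusted p = 0.6 with an estimated correlation. These values also join unlike groups. In magn[12c]/magn[23b] and magn[12c]/magn[12c];pSC2, ORY read -2.55 and -5.76, Ppr-Y -2.5 and -4.75, Dhc36C -2.46 and -4.91, and Dhc16F -2.57 and -3.61. Dhc62B, Dhc98D and alphaTub85E were instead lower in magn[12c]/magn[23b]. Other magn values here are likewise means over the 2 combinations, which are compared below. Comet and cup genes fell in 7 of 14 cases (7 adjusted over the list alone; t-cup -3.16, d-cup -2.36; camera adjusted p = 6.51e-05), with adjusted p = 0.6 with an estimated correlation. The d-cup level was 9.93 and 9.86 in the magn[12c]/magn[23b] arrays and 7.51 and 7.55 in those of magn[12c]/magn[12c];pSC2. Testis mitochondrial paralogs fell in 10 of 15 cases and rose in 1 (the same counts adjusted over the list alone; COX6AL -3.56), with a camera adjusted p of 0.00153, and adjusted p = 0.6 with an estimated correlation. Testis proteasome paralogs fell in 6 of 13 cases and rose in 1 (the same counts adjusted over the list alone), with Prosalpha3T at -2.63 and Prosbeta4R2 at least 1.69-fold higher and not called with values under 4 raised to 4 (0.76). Camera gave 0.0498, and adjusted p = 0.667 with an estimated correlation. Taken alone, magn[12c]/magn[23b] had 2 of the 13 lower and 1 higher, the same adjusted over the list alone, and the list was not called (camera adjusted p = 0.156). In magn[12c]/magn[12c];pSC2 6 were lower and 1 higher, the same adjusted over the list alone (camera adjusted p = 0.00453), with adjusted p = 0.478 with an estimated correlation. Of 5 sperm leucyl aminopeptidase genes 1 fell, also 1 adjusted over the list alone (camera adjusted p = 0.00659), with adjusted p = 0.6 with an estimated correlation. After centring on ribosomal protein genes the genes called lower were 7 of 8 for sperm chromatin, 14 of 16 for the axoneme, 14 of 14 for comet and cup, 11 of 15 for the mitochondrial paralogs, 9 of 13 for the proteasome paralogs and 5 of 5 for the aminopeptidases.

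Of 5 testis TAF genes 4 rose (4 adjusted over the list alone; nht 1.65 and Taf12L 1.51, or 0.67 and 0.53 after centring on ribosomal protein genes, which left 0 of the 5 called), while can read 0.32, or -0.66 with arrays centred on ribosomal protein genes and -0.05 with arrays centred on all genes. Camera gave 0.0323, and adjusted p = 0.6 with an estimated correlation. Of the tMAC genes 6 of 9 rose (6 adjusted over the list alone), or 1 higher and 1 lower after that centring. That list was not called (camera adjusted p = 0.0918), and topi at -0.53 did not pass. The germline genes bam (2.19) and qin (2.91) and the blood cell genes Hml (3.87, or 3.63 with values under 4 raised to 4) and Pxn (2.89) rose. The stem cell and spermatogonia list (8 of 15 higher, 1 lower, the same counts adjusted over the list alone) was not called (camera adjusted p = 0.191), and its median of 1.00 became 0.02 after that centring. Hemocyte genes were higher in 4 of 6 cases (4 adjusted over the list alone), or 2 after that centring, and the list was not called (camera adjusted p = 0.0918). The hemocyte array medians were 7.83 to 8.73 in magn and 6.08 to 6.57 in WT. General proteasome genes rose in 9 of 26 cases (9 adjusted over the list alone; Prosbeta2 by 2.01), with a median of 0.63 that became -0.35, with 1 higher and 1 lower, with arrays centred on ribosomal protein genes. Camera gave 0.000324, and adjusted p = 0.6 with an estimated correlation. Ribosomal protein genes rose in 18 of 36 cases and fell in 2 (the same counts adjusted over the list alone; RpL37-2 2.21), with a camera adjusted p of 1.05e-05, and adjusted p = 0.6 with an estimated correlation. The hub gene esg was at least 10.1-fold lower. With arrays centred on ribosomal protein genes, a shift of 0.98, 704 genes were higher and 3034 lower, and 18.8% of the calls were higher in place of 67.1%. The 13 lists not called in magn had camera adjusted p from 0.0918 to 0.983. Among them were meiotic cell cycle genes (median 0.10, and -0.88 after centring on ribosomal protein genes), meiotic chromosome genes (0.85 and -0.13, and 0.25 with dim genes at their bound), spermatocyte genes (0.16 and -0.82), cyst and hub cell genes (0.47 and -0.51), heat shock genes (0.32 and -0.65), apoptosis genes (0.50 and -0.47) and fat body genes (-0.60 and -1.58). The lists of accessory gland (0 of 20 called) and sheath muscle genes (2 higher, 2 lower of 14; median 0.31, and -0.67 after that centring) were not called either. The accessory gland median was 12.05 and 12.22 in the magn[12c]/magn[12c];pSC2 arrays against 8.78 and 8.13 in the magn[12c]/magn[23b] arrays. The count of 0 joins 2 unlike groups. Against WT, 11 of the 20 were lower in magn[12c]/magn[23b], also 11 adjusted over the list alone, with a median of -1.98, or -1.87 with dim genes at their bound (camera adjusted p = 0.000361), and adjusted p = 0.681 with an estimated correlation. In magn[12c]/magn[12c];pSC2 none was called (0 adjusted over the list alone), the median was 1.04, or -0.05 after centring on ribosomal protein genes, and the list was not called (camera adjusted p = 0.8).

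**Figure D2:**
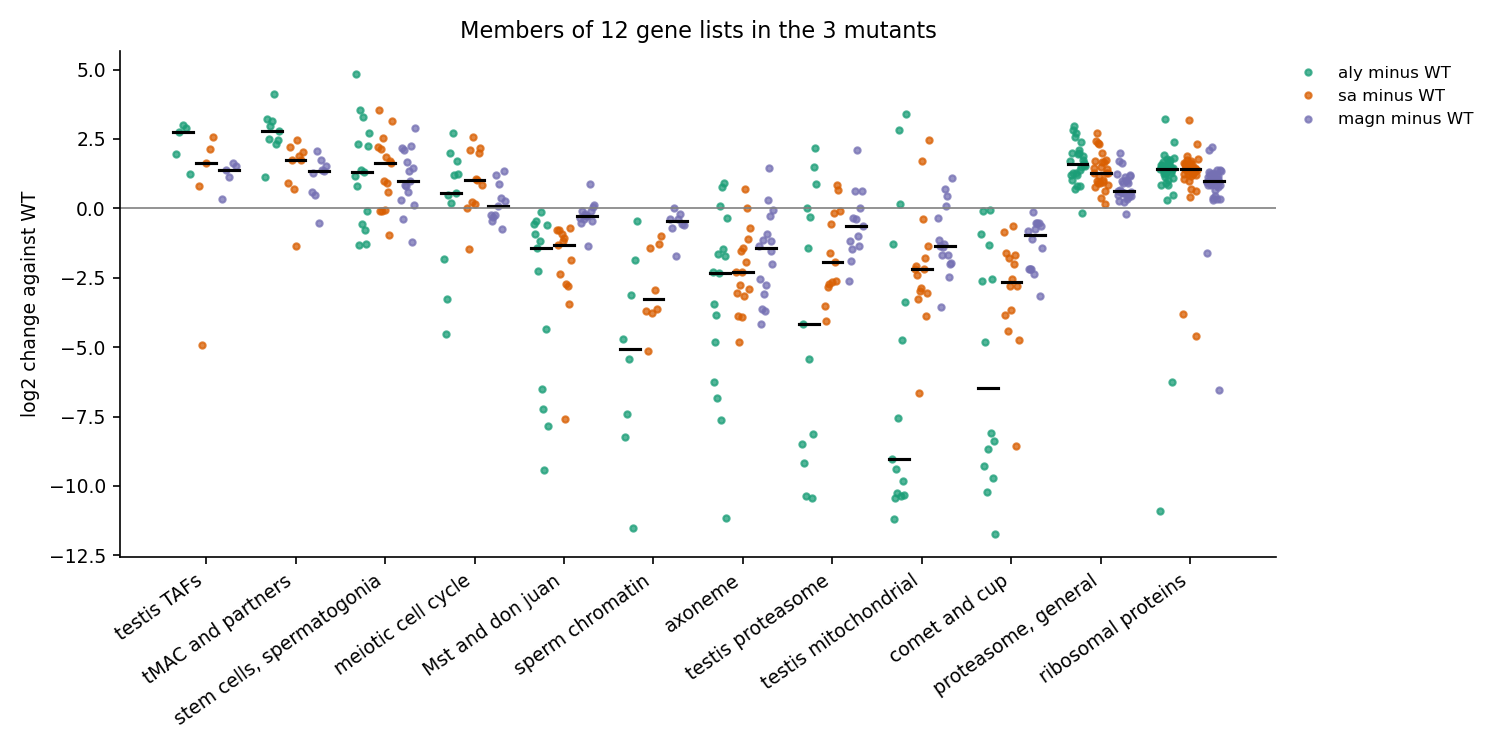
Log2 change of each measured member of 12 gene lists in aly, sa and magn testes against WT (vertical axis, log2; points are genes, black bars are list medians). The medians of late germline lists lie below 0 (comet and cup -6.46 in aly, or -5.85 with dim genes at their bound, -2.67 in sa and -0.96 in magn), while the general proteasome list lies above 0 (medians 1.60, 1.28 and 0.63), which became 0.18, -0.13 and -0.35 with arrays centred on ribosomal protein genes.

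The overlap of the mutants was counted next, because the comparisons share the 3 WT arrays. Of the 2121 genes lower in aly and the 1857 lower in sa, 1655 were lower in both, against 452 if the calls were independent. Simulated unchanged groups that share simulated WT arrays gave 0 on average. That value follows from having no changed genes, and it does not measure what the real WT arrays bring to the overlap. Higher in both were 2997 genes, against 1620 if independent, and 52 genes were called in opposite directions. Across genes, which are not independent replicates, the changes in aly and sa had a Pearson's r of 0.84 (Spearman's rho 0.84), against 0.50 for simulated unchanged groups, and a covariance of 6.25 against a simulated 0.0624. For aly and magn 1001 genes were lower in both (304 if independent; r 0.61 against a simulated 0.53; covariance 3.31 against 0.0623), and for sa and magn 1013 (266 if independent; r 0.75 against 0.54; covariance 2.35 against 0.0633).

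The 1655 genes lower in both aly and sa, such as dj, ProtB, w-cup and COX5BL, were then followed in magn. Their median log2 change was -6.34 in aly, -2.77 in sa and -1.24 in magn (quartiles -2.24 and -0.51), or -5.77, -2.71 and -1.20 with values under 4 raised to 4. In magn 934 of them (56.4%) were called lower, 697 were not called and 24 were higher. Set against the other mutants directly, 1356 were called higher in magn than in aly, 1047 higher in magn than in sa, and 1003 higher than in both, while 12 were below both. The combination of not being lower than WT and being higher than in both other mutants held for 607 genes. The set was chosen on the aly, sa and WT arrays, and the same WT arrays enter the magn values. Of the 2997 genes higher in both aly and sa, 1740 (58.1%) were also higher in magn. With arrays centred on ribosomal protein genes the number of genes lower in both aly and sa became 3069, of which 2161 were lower in magn.

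**Figure D3:**
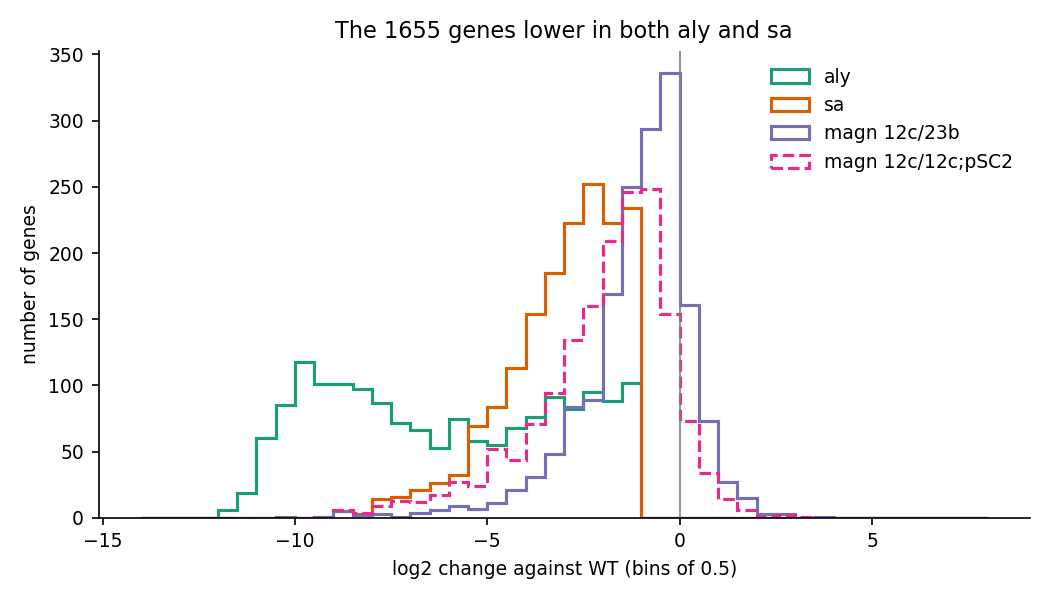
Distribution of the log2 change against WT (horizontal axis, bins of 0.5) of the 1655 genes called lower in both aly and sa (vertical axis, number of genes), in aly, in sa and in each magn allele combination. The median is -6.34 in aly (-5.77 with values under 4 raised to 4), -2.77 in sa, -0.84 in magn[12c]/magn[23b] and -1.60 in magn[12c]/magn[12c];pSC2.

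The difference between aly and sa was tested directly. The sa transcript was 7.66 higher in aly (SE 0.16), as were Alp8 (at least 17.2-fold), an alkaline phosphatase gene, the cuticle gene Cpr76Bc (at least 15.9-fold), the D-amino acid oxidase gene Daao2 (at least 11.5-fold), 18SrRNA-Psi:CR41602 (at least 14.6-fold) and Patsas (log2 difference 5.14, or 4.74 with values under 4 raised to 4). The largest fitted falls in aly against sa were those of tomboy20, a mitochondrial import paralog (at least 218-fold), COX5BL (at least 142-fold), Prosbeta5R1 (at least 132-fold), Tektin-A (at least 168-fold), robl62A (at least 153-fold) and Atg8b (-8.25, or -7.98 with values so raised), with n = 3 and 3 and adjusted p of at most 6.84e-11 (limma). The regulators CycB (-5.36), bol (-3.04) and twe (-1.82) were lower in aly than in sa, and topi was 4.50 higher. After quantile normalization twe read -0.91 and was not called. In total 3427 genes were called, 1619 higher and 1808 lower in aly, and 565 were at least 16-fold lower with values under 4 raised to 4. Camera called 3 of 23 lists. The testis mitochondrial paralogs were lower in aly (11 of 15 lower, 1 higher, the same counts adjusted over the list alone; adjusted p = 0.00475), with adjusted p = 0.993 with an estimated correlation. Sperm chromatin genes were lower in 5 of 8 cases, also 5 adjusted over the list alone (camera adjusted p = 0.0274), and tMAC genes higher in 4 of 9, also 4 adjusted over the list alone (camera adjusted p = 0.0235), both with adjusted p = 0.993 with an estimated correlation. Not called were the axoneme (median -0.02), spermatid Mst and don juan (0.12) and leucyl aminopeptidase (0.67) lists, with camera adjusted p of 0.707, 0.819 and 0.993. The comet and cup and the testis proteasome paralog lists were not called either.

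The difference between magn and aly was tested in the same way. Late transcripts were far higher in magn: Mst33A stood at 13.93 ± 0.20 (n = 4) against 2.63 ± 0.07 (n = 3), at least 978-fold higher, followed by saturn (at least 812-fold), ATPsynCF6L (at least 774-fold), Rcd7 (at least 510-fold), w-cup (at least 389-fold) and c-cup (at least 544-fold). Also higher were dj (at least 91.0-fold), ProtB (log2 difference 7.53) and Prosbeta5R1 (at least 252-fold), and the meiotic regulators bol (4.08), CycB (2.97) and twe (1.59), with adjusted p of at most 4.87e-05 (limma). After quantile normalization twe read 0.61 and was not called. Lower in magn were Ubi-p63E (-10.49, or -10.34 with values under 4 raised to 4), Patsas (at least 28.4-fold), Rif1, a replication timing gene (at least 37.2-fold), the peptidase gene Nepl4 (at least 31.1-fold), the receptor gene Ir76a (at least 41.2-fold) and htk (-5.58). In total 5157 genes were called, 2248 higher and 2909 lower, and 928 were at least 16-fold higher in magn with values under 4 raised to 4. With arrays centred on ribosomal protein genes 56.6% of the calls were higher in place of 43.6%. Camera called 8 of 23 lists, among them the sperm chromatin genes (7 of 8 higher, 7 adjusted over the list alone; adjusted p = 0.000681), the spermatid genes (7 of 13, 7 adjusted over the list alone; adjusted p = 0.000686) and the comet and cup genes (9 of 14 higher, 1 lower, the same counts adjusted over the list alone; adjusted p = 0.00134), each with adjusted p = 0.643 with an estimated correlation. Sheath muscle genes were also higher in magn than in aly (6 of 14, 6 adjusted over the list alone; camera adjusted p = 0.0298), with adjusted p = 0.643 with an estimated correlation. Accessory gland genes were higher in 7 of 20 cases, or 1 adjusted over the list alone, and that list was not called (camera adjusted p = 0.0907). Of the sheath muscle genes 10, and of the accessory gland genes 12, were higher after centring on ribosomal protein genes. Of the 8 lists that camera called, 6 were higher and 2 lower in magn. The actin 5C 3' minus 5' signal was 2.27 to 2.73 in the aly arrays, 1.72 to 1.86 in 3 magn arrays and 3.21 in the remaining magn array.

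The difference between magn and sa was smaller than that between magn and aly by count, with 3295 genes called, 1624 higher and 1671 lower in magn, and 73.2% higher in place of 49.3% with arrays centred on ribosomal protein genes. Camera called 8 of 23 lists, 6 of them higher and 2 lower in magn. Comet and cup genes were higher in magn in 10 of 14 cases (10 adjusted over the list alone; camera adjusted p = 0.000623), with adjusted p = 0.722 with an estimated correlation. Sperm chromatin genes were higher in 6 of 8 cases (6 adjusted over the list alone; camera adjusted p = 1.61e-05) and spermatid Mst and don juan genes in 6 of 13 (6 adjusted over the list alone; camera adjusted p = 1.86e-06), both with adjusted p = 0.665 with an estimated correlation. Sheath muscle genes were higher in 4 of 14 cases, also 4 adjusted over the list alone (camera adjusted p = 0.0176), with adjusted p = 0.722 with an estimated correlation. Centring on ribosomal protein genes gave 12 of 13 for the spermatid and 10 of 14 for the sheath muscle genes. The actin 5C 3' minus 5' signal was 4.76 in sa replicate 3, without which 2982 genes were called between magn and sa.

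The 4 magn arrays combine 2 allele combinations, which were compared with each other. In magn[12c]/magn[23b] testis proteasome paralogs were higher than in magn[12c]/magn[12c];pSC2 in 6 of 13 cases (6 adjusted over the list alone; camera adjusted p = 2.56e-05), with adjusted p = 0.393 with an estimated correlation, and comet and cup genes in 5 of 14 (5 adjusted over the list alone; camera adjusted p = 1.94e-05), with adjusted p = 0.222 with an estimated correlation. Accessory gland genes were lower in 13 of 20 cases, or 18 adjusted over the list alone, with a median of -2.94 (camera adjusted p = 1.04e-07), and adjusted p = 0.517 with an estimated correlation. In total 879 genes were called with n = 2 and 2 arrays, 692 higher and 187 lower in magn[12c]/magn[23b], and 476 without magn[12c]/magn[12c];pSC2 replicate 2. Against WT, magn[12c]/magn[23b] had 3301 called genes (2219 higher, 1082 lower) and magn[12c]/magn[12c];pSC2 had 4273 (2810 higher, 1463 lower). With arrays centred on ribosomal protein genes these splits became 684 higher and 2797 lower, and 735 higher and 3320 lower, and the split between the combinations 845 higher and 95 lower. The actin 5C 3' minus 5' signal was 3.21 in magn[12c]/magn[12c];pSC2 replicate 1 and 1.72 to 1.86 in the other magn arrays.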

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

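The tests of other groupings of the arrays, the choice of the array signals examined, and the tests of the axoneme genes and of the magn allele difference were chosen only after the results were seen. The comparisons between mutants were planned.

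Direct tests between groups differed for many genes: 3427 genes between aly and sa, 5157 between magn and aly, 3295 between magn and sa and 879 between the 2 magn allele combinations (limma). Among the genes named here, some were called in opposite directions against WT in 2 mutants. For aly minus sa these were CycB (-5.36), Daao2 (5.36), sa (7.66) and topi (4.50). For magn minus aly they were Daao2 (-5.39) and Ir76a (-5.92), and for magn minus sa they were Ir76a (-4.21) and sa (6.31). The value of sa compares with arrays that carry sa mutations. Values of Daao2 and Ir76a are fitted differences against groups at background and not measured sizes. Daao2 lay at or below 4 in all sa and magn arrays, so its differences from aly are at least 11.5-fold, and its calls as lower than WT in sa and magn do not hold on that bound (-0.49). Ir76a lay at or below 4 in all magn arrays, at least 41.2-fold below aly and at least 3.1-fold below WT. Probe sets that pair with no gene name were left out of the comparisons, and 448 of 1089 were called higher than WT in aly, 435 in sa and 320 in magn. The 4 magn arrays were examined for 1 array apart from the others, which chance gives in about 1 of 20 cases. Of 107 genes named in the texts, 96 lay above 4 in any magn array and none of these had an array apart, and among all 8376 tested genes above 4 in any magn array there were 385 (4.6%). Of 4 array signals examined, 1 had an array apart: the actin 5C 3' minus 5' signal, at 3.21 in magn[12c]/magn[12c];pSC2 replicate 1 against 1.72, 1.82 and 1.86.

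Arrays were split into groups of the same sizes in every other way. For the 3 against 3 comparisons the 10 splits are too few for a share under 0.05: the real split gave 6087 called genes for aly against WT, 5412 for sa against WT and 3427 for aly against sa, and the highest other split gave 0 in each, so that 1 of 10 splits gave as many. The same limit holds for the lists called, 13 in aly with 12 as the highest other (1 of 10 splits gave as many) and 10 in sa with 12 as the highest other (9 of 10). For magn only the real split, 1 of 35, gave as many genes called, which is the smallest share this test can give. The counts were 3792 against WT with 2936 as the highest other, 5157 against aly with 4128, and 3295 against sa with 2385. These shares were not corrected for the number of comparisons. Chance was not excluded for the number of lists called in magn, 10 against WT with 13 as the highest other (6 of 35 splits gave as many) and 8 against aly with 11 (15 of 35). Among 100 regroupings, 1 (the real one) gave as many as the 1655 genes lower in both aly and sa, where the highest other gave 1467, and 1 gave as many as the 934 lower in all 3 mutants, where the highest other gave 100. Swapping the labels of aly and sa leaves both counts unchanged by construction, and that regrouping was not among those drawn. Other regroupings can still keep the WT arrays, or those of another genotype, together. Which one gave 1467 was not recorded, so it need not be a value for fully mixed arrays.

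Axoneme genes fell in magn (10 of 16 lower, 1 higher, or 14 lower with arrays centred on ribosomal protein genes). Of the 11 members outside the Y, 6 were lower and 1 higher (tilB, 1.45), with a median of -1.19 (95% interval over genes -2.77 to -0.05). A different Y chromosome in the WT strain that changes only its own genes does not give these falls. They cannot decide on an effect of the Y on genes elsewhere, because the Y goes with the genotype. For the 5 Y-linked members, of which 4 were lower, the median of -2.53 cannot be told apart from such a difference, because the Y chromosome goes with the genotype in these arrays. RNA breakdown in the magn arrays is argued against by magn[12c]/magn[23b], whose actin 5C 3' minus 5' signal of 1.72 and 1.82 is near that of WT. Its list median was -1.35 (95% interval over genes -2.46 to -0.43). An effect of the magn mutations on these genes stays open. So do an effect of the Y on genes elsewhere and a strain difference outside the Y, neither of which was tested.

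The genes lower in both aly and sa were lower in magn[12c]/magn[12c];pSC2 than in magn[12c]/magn[23b], with array medians against WT of -1.54 and -1.67 in the former and -0.94 and -0.72 in the latter. RNA breakdown in replicate 1 of the former does not by itself give this difference, as far as 1 other array can show. Replicate 2 alone lay at -0.81 from the mean of the latter (95% interval over genes -0.87 to -0.77). WT RNA in the magn[12c]/magn[23b] arrays would need a share of 34.4% and a Ubi-p63E level of 13.22, where the highest array read 5.47, so it is excluded. The difference between the combinations was lower for these genes than for the 20 other genes of nearest level, by a median of -0.96 (95% interval -1.01 to -0.93). A change shared by all genes would give 0. This cannot decide on accessory gland RNA, because only the accessory gland list was left out of the matched genes. Genes active in both tissues would not be diluted alike. The accessory gland medians were 12.05 and 12.22 in magn[12c]/magn[12c];pSC2 and 8.78 and 8.13 in magn[12c]/magn[23b]. Whether alleles, the pSC2 construct, accessory gland RNA or the background cause the difference stays open.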

How the results depend on the processing

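Of the alternatives, 2 were chosen after seeing the data: leaving out the 2 arrays with the lowest 5' actin signal (sa replicate 3 and magn[12c]/magn[12c];pSC2 replicate 1), and raising values under 4 to 4. For the changes below the cause was not tested unless stated. List values are the list's median minus that of all genes, and a list is called reversed when the direction of its test changed.

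Called genes were kept in the same direction in 89.2% to 98.5% of cases without a filter or with a stricter one or after quantile normalization in aly and sa against WT, and in 80.2% to 97.2% in magn against WT, with 0 called in the opposite direction. Centring on ribosomal protein genes kept 63.4% in aly, 50.8% in sa and 51.5% in magn. Here too 0 were opposite, but this was fixed in advance. The shifts of 1.41, 1.41 and 0.98 are too small to turn a 2-fold call into a 2-fold call the other way.

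That centring moves every gene by the same shift, which gave 1738 higher and 3750 lower in aly, 893 and 3769 in sa, 704 and 3034 in magn, 684 and 2797 in magn[12c]/magn[23b] and 735 and 3320 in magn[12c]/magn[12c];pSC2, all against WT. It gave 815 lower in magn than in sa, 95 lower between the allele combinations, and 3069 genes lower in both aly and sa, of which 2161 were lower in magn. It reversed aly in aly (-0.29), magn (-0.40) and sa (-0.50), Taf12L in aly (-0.17), dj in magn (-0.10), can in magn (-0.66) and sa (-0.60), the meiotic cell cycle list in aly (-0.22) and magn (-0.28), heat shock in magn (-0.06) and ubiquitin in magn against aly (0.24). Centring on all genes gave 1649 higher in magn and 1331 in magn[12c]/magn[23b], and reversed can (-0.05) and the meiotic cell cycle list (-0.28) in magn.

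Without a fold minimum, more genes pass by construction: 2508 higher in aly than sa, 5170 between magn and sa (3092 lower), 3331 higher in magn[12c]/magn[23b] than WT, and 1431 between the allele combinations (498 lower). With treat, which tests against 2-fold and so calls fewer, there were 2331 higher in sa, 1675 in magn (1042 higher, 633 lower), 1888 between aly and sa (617 higher), 1868 lower in magn than aly, 1349 between magn and sa (815 higher, 534 lower), 1221 in magn[12c]/magn[23b] (772, 449), 2296 in magn[12c]/magn[12c];pSC2 (1357, 939), 114 between these (109, 5), and 460 genes lower in all 3 mutants.

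The lists that reversed were not called in the report. The meiotic cell cycle list in magn became -0.47 with the stricter filter and with array weights, and read -0.28 with the test reversed without the trend, with only the arrays compared and with 5 groups. Array weights also reversed sheath muscle (0.65) and accessory gland (1.2) in magn. Quantile normalization reversed ubiquitin in sa (-0.39), magn (-0.22) and magn against aly (0.42), and in the last also cyst and hub (0.08) and fat body (-0.39), the latter 0.03 without a filter. Leaving out probe sets shared by transcripts reversed ubiquitin in aly (0.38), sa (0.16), magn (0.38) and magn against aly (0.29), heat shock in aly (-0.04) and magn against aly (-0.25), spermatocyte in magn (-0.07) and magn against aly (-0.01), and cyst and hub in the last (0.02). With only the arrays compared, ubiquitin in magn against aly was 0.24.

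Camera with an estimated correlation called 0 lists in aly, sa and magn against WT and 0 in magn against aly (limma), where fry called 20, 20, 16 and 16. Fry's direction was the opposite for ubiquitin in aly (-0.82) and sa (-0.75), heat shock in aly (-0.86), spermatocyte (-0.22) and sheath muscle (-0.07) in magn, and cyst and hub in magn against aly (-0.02).

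Leaving out each array in turn gave 5946 to 6133 genes in aly, 5286 to 5438 in sa, 3564 to 3995 in magn, 3091 to 3710 between aly and sa, 5026 to 5229 between magn and aly, 2982 to 3483 between magn and sa, and 1618 to 1678 lower in both aly and sa, of which 854 to 1020 were lower in magn. The allele combinations gave 476 (without magn[12c]/magn[12c];pSC2 replicate 2) to 1007 genes, 401 to 725 higher and 75 to 283 lower. The lower count was 83 without magn[12c]/magn[12c];pSC2 replicate 1, 75 without its replicate 2 and 283 without WT replicate 2. Where an arm then has 1 array, it is assumed to vary like the other groups. Without WT replicate 2, ubiquitin reversed in aly (-0.79, range -0.86 to -0.78) and magn (-0.20, range -0.61 to -0.20), as did sheath muscle in magn (0.17, range -0.32 to 0.17). The meiotic cell cycle list in magn ranged from -0.46 to -0.20 and reversed without sa replicate 1 or 3 (-0.28 each), magn[12c]/magn[23b] replicate 2 (-0.46) or WT replicate 2 (-0.34). Values near 0 that changed sign were twe in sa (range -0.09 to 0.11; 0.08 without sa replicate 3, 0.11 without WT replicate 3), CycB in magn (range -0.63 to 0.09, the latter without magn[12c]/magn[12c];pSC2 replicate 2) and Ubi-p63E in aly (range -0.11 to 0.01, the latter without WT replicate 3). The calls of bol in sa (-0.93 without sa replicate 3) and Dup99B in aly (-4.03 without aly replicate 3, -4.11 without WT replicate 2) ended.

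Without the 2 arrays of low 5' actin signal, 97 genes were lower between the allele combinations and twe in sa was 0.08. With values under 4 raised to 4, all counts stayed within 1.5 times those reported. With a replicate block the counts for aly vs WT, sa vs WT and magn vs WT were 6075, 5407 and 3765. Signal over background limits both falls and rises. Counting calls in both directions against WT, 1271 in aly, 460 in sa and 412 in magn had a group at or below 4. Of these, 1111, 298 and 254 were at least 2-fold on the bound.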

Other observations

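The tests of chromosome 4 genes were chosen only after the result was seen, and so were the genes named in this part.

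Genes that changed at least 16-fold in the same direction in all 3 mutants with values under 4 raised to 4, and whose mutant means lay within 1.5 log2 units of each other, numbered 28 lower and 1 higher. Of the 28, 6 had all 3 mutant means above 4, and in the others at least 1 mutant was at background, where agreement of the means says nothing about a shared level. Cap-G fell from 10 in WT to 5.95 in aly, 5.11 in sa and 5.72 in magn. TbCMF46 fell from 8.27 and ODA-Dnal1 from 8.34 to mean values at background in all 3. The gene chm rose from 4.92 to 10.52, 9.17 and 9.36. A difference between the WT strain and the others stays open for these genes and was not tested.

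Sc2, a neighbour of Ubi-p63E, read 11.17 ± 0.03 (SD, n = 3) in WT, 13.11 ± 0.10 in aly (n = 3), 13.01 ± 0.04 in sa (n = 3) and 10.95 ± 0.07 in magn (n = 4).

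Of 1351 tested genes on the X chromosome, 11% were higher and 28.4% lower in magn than in sa, against 20% and 17.5% of genes elsewhere (Fisher's exact test, two-sided, adjusted p = 1.53e-14 and 1.12e-17 over 108 tests). The tests by chromosome, here and below, take genes as units. Genes are not independent replicates, so these p-values do not measure the spread between arrays. Against WT, 52% of X-linked genes were higher in aly and 44.3% of others (Fisher's exact test, adjusted p = 3.06e-06). The shares were 47% and 39.6% in sa (Fisher's exact test, adjusted p = 5.2e-06) and 27% and 29.6% in magn (Fisher's exact test, adjusted p = 0.152). X-linked genes were less often lower than others in all 3 mutants: 19.1% against 25.3% in aly (Fisher's exact test, adjusted p = 1.05e-05), 15.9% against 22.3% in sa (Fisher's exact test, adjusted p = 1.49e-06) and 11.2% against 14.9% in magn (Fisher's exact test, adjusted p = 0.00151).

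Of 41 tested genes on chromosome 4, 24 were higher and 1 lower in magn than in WT (58.5% higher, against 29.0% of genes elsewhere; Fisher's exact test, two-sided, adjusted p = 0.000509 over 108 tests). Their array medians against WT were 1.34, 1.10, 1.24 and 1.16 in the 4 magn arrays, where those of all tested genes were 0.35, 0.31, 0.5 and 0.42. In aly the chromosome 4 medians were -0.47, -0.53 and -0.37 (all tested genes 0.81, 0.7 and 0.81). In sa they were 1.05, 0.61 and, in replicate 3, which has the lowest 5' actin signal, -0.25 (all tested genes 0.62, 0.71 and 0.62). A copy number of 3 in place of 2 for chromosome 4 in magn flies may be part of this and stays open. The median of these genes exceeded that of all tested genes by 0.90 (95% interval 0.47 to 1.19), which holds the 0.58 that 3 copies against 2 would give. Chromosome 4 genes also moved in aly, though, and in the opposite direction, by -0.87 (-1.60 to -0.42) against the 20 genes of nearest span on other chromosomes, with -0.18 (-0.87 to 0.15) in sa. Between magn and aly that value was 2.03 (1.51 to 2.35), more than 3 copies against 2 would give, so such a copy number in magn alone does not account for all differences of these genes. Gene span as the whole cause is argued against: chromosome 4 genes have a median span of 9.27 kb against 2.33 kb over all tested genes, and they exceeded the 20 genes of nearest span on other chromosomes by 0.55 (0.27 to 0.87). A difference in the regulation of chromosome 4 genes was not tested and stays open.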
